A study of Danio rerio with 7 samples.

How the data were processed

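ChIP-seq was run on whole zebrafish embryos of the Tu strain at the bud stage for 4 targets: Cdx4 and Sall4, both Myc-tagged and precipitated with an antibody against the tag, H3K27ac and H3K4me3. Per the labels' protocols, 2000 embryos were staged per experiment, 500 were collected and dissociated, the extract was crosslinked in 1.1% formaldehyde for 15 min, and embryos were uninjected or had received mRNA at the 1-cell stage. There was 1 library per target and there were 3 input libraries, which were not analysed here. With no replicates of any ChIP target, no comparison has a spread between libraries.

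The files used were interval lists, not reads. The authors deposited a list of peaks for each factor and a list of domains for each mark, with a score per interval whose meaning is not given in the sources used here. It was used only to rank intervals within a list. Per the interval names in the deposited lists, Cdx4 and Sall4 peaks carry the prefix of the GPS peak caller, and domains carry no caller's name. Bowtie 0.12.7 and CASAVA 1.4 are named in the submitters' processing notes, per the labels, without their roles. The peak thresholds, the use of the input libraries, filters and sequencing depth are not given in the sources used here. Each deposited list was made from 1 library, per the labels. The number of peaks in a list therefore depends on depth and thresholds that are unknown, and differences in list length were not read as differences in binding. The deposited scores ran from 26 to 1028 for Cdx4, 29 to 558 for Sall4, 0 to 4411 for H3K27ac and 0 to 3318 for H3K4me3.

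Scaffold names in the deposited lists carry the prefix of zebrafish assembly Zv8. Coordinates were read as counted from 1 with both ends included, because 12 domains start at position 1 and 0 intervals start at position 0. Read this way every peak is 100 bp wide, and peaks were used as deposited. The lists reached 997 sequences and 1363.56 Mb in all. The length of each sequence was taken as the last position that any of the 4 lists reached. The only annotation tables at hand were of another assembly, so distances to transcription start sites, counts over gene lists and motif matches, which had been planned, were not run, and no gene was assigned to an interval. In place of genes the text names positions by a rule for this case: the 10 top-scoring peaks of each factor, the 10 overlapping pairs with the highest combined rank and the 5 widest domains of each mark. The groups, the main comparisons with their tests, and this rule were fixed before the data were examined. The comparison of Cdx4-only with Sall4-only peaks, the comparisons within score groups and several tests of explanations were chosen later.

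Intervals counted as overlapping when they shared at least 1 bp. A peak that overlapped a peak of the other factor was called shared, and any other peak single-factor or, for example, Cdx4-only. Shares were given with exact (Clopper-Pearson) binomial 95% intervals, which cover counting error only. As a background, the intervals of a list were shifted by a random distance around each sequence 1000 times. Differences between shares were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 14 comparisons, and given a 95% interval from 1000 bootstrap draws of 1 Mb blocks. Peaks of 1 list are not independent replicates, so the block intervals were given more weight than the p-values. Lists were ranked by score and divided into 4 groups of equal size. Dense windows were tiles of 100 kb with 5 or more peaks, set beside 1000 random placements. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

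The overlap count and the bootstrap were tested on simulated data. With 400 overlaps planted among 5166 simulated peaks, 400 were found along with 4 that arose by chance, where shifts gave a mean of 7.34. In 100 simulations with a true difference of 10 points, the bootstrap interval covered it in 93 and excluded 0 in 100. With no true difference the interval excluded 0 in 10 of 100 simulations, so intervals that only just exclude 0 were read with caution. Coverage where neighbouring peaks are alike, or where the lists share sites, is not shown by these simulations.

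Alternatives covered the overlap definition, the part of the list used by score, the number of top peaks, the domain widths, the background and the window layout. Widening peaks to 200 bp, keeping only H3K27ac domains over 500 bp wide, and the alternatives for the comparison of Cdx4-only with Sall4-only peaks were added after the data were seen.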

Results

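Binding sites of Cdx4 and Sall4 and domains of 2 histone marks were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole zebrafish embryos of the Tu strain at the bud stage, the end of gastrulation. Cdx4 is a homeodomain transcription factor of the caudal family and Sall4 a zinc finger transcription factor of the spalt family. Both factors carried a Myc tag and were precipitated with an antibody against the tag. Embryos were injected with mRNA at the 1-cell stage or left uninjected, and the sources used here do not say which, library by library. A Myc-tagged factor is not the endogenous protein, so injected mRNA is its likely source in the Cdx4 and Sall4 libraries. Their peaks are sites of tagged protein, which may differ from sites of the endogenous factors. H3K27ac, an acetylated histone found at active enhancers and promoters, and H3K4me3, a methylated histone found at promoters, were precipitated with their own antibodies. The study concerns how Cdx4 and Sall4 act together as mesoderm gives rise to blood. Each target was represented by 1 library and 1 list of intervals, and 3 input libraries were not analysed here.

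The deposited lists held 5166 Cdx4 peaks, 9747 Sall4 peaks, 4599 H3K27ac domains and 19401 H3K4me3 domains. Every Cdx4 and Sall4 peak was 100 bp wide. The median domain width was 399 bp for H3K27ac (quartiles 299 and 499 bp) and 699 bp for H3K4me3 (quartiles 399 and 1099 bp). H3K27ac domains covered 2.18 Mb and H3K4me3 domains 15.0 Mb. Between 92.6% and 95.2% of the intervals of each list lay on the 25 assembled chromosomes of zebrafish assembly Zv8, and the rest on unplaced scaffolds. Sequencing depth was not given in the sources used here. None of the 4 ChIP targets had a replicate, so no value below carries an error between embryos or libraries, and the intervals and tests describe differences within these 4 lists.

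The overlap of Cdx4 and Sall4 binding bears on whether both factors occupy the same sites. Of the Cdx4 peaks, 2351 of 5166 (45.5%, exact binomial 95% interval 44.1 to 46.9%) overlapped a Sall4 peak by at least 1 bp. In the other direction, 2317 of 9747 Sall4 peaks (23.8%, 22.9 to 24.6%) overlapped a Cdx4 peak. When the Cdx4 peaks were shifted along each sequence, a mean of 14.7 and at most 28 of them overlapped a Sall4 peak in 1000 shifts. Peaks that overlapped formed 2274 one-to-one pairs, whose centres lay a median of 25 bp apart (quartiles 12 and 46 bp). In 1154 pairs (50.7%) the centres were within 25 bp of each other, against 25.6% for peaks placed anywhere within an overlap. Across pairs, which are not independent replicates, the Cdx4 and Sall4 scores had a Spearman correlation of 0.255 (bootstrap 95% interval 0.210 to 0.299). The excess over shifted peaks was 160-fold for Cdx4 peaks, with the smallest p that 1000 shifts can give (0.001), and it ranged from 44.1-fold with centres within 500 bp to 316-fold on assembled chromosomes alone. Both factors were precipitated with the same anti-Myc antibody, and no anti-Myc precipitation from untagged embryos was used here.

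The highest-scoring peaks of each list mostly overlapped a peak of the other factor. All 10 top-scoring Cdx4 peaks and 8 of the 10 top-scoring Sall4 peaks overlapped a peak of the other list. The highest Cdx4 score, 1028, was on chromosome 8 at 20136771 to 20136870, within an H3K27ac domain and overlapping a Sall4 peak with a score of 244. A site on chromosome 20 ranked at the top of the Sall4 list (33284886 to 33284985, score 558) and next to the top of the Cdx4 list (33284797 to 33284896, score 763). That site lay 13599 bp from the nearest H3K27ac domain and 24004 bp from the nearest H3K4me3 domain. Among the other top Cdx4 peaks, those on chromosome 15 at 19834180 to 19834279 (score 617) and on chromosome 23 at 22802889 to 22802988 (score 495) lay in H3K27ac domains. The Cdx4 peak on chromosome 13 at 43947871 to 43947970 (score 504) lay in domains of both marks. Of the 10 pairs with the highest combined rank, 4 were in an H3K27ac domain and 0 in an H3K4me3 domain. These pairs included chromosome 14 at 39053427 (Cdx4 score 393, Sall4 score 385), chromosome 13 at 50024520 (361 and 348), chromosome 6 at 49442307 (284 and 389) and chromosome 7 at 7456386 (298 and 304), each position being the start of the Cdx4 peak. The last 2 of these were in H3K27ac domains. No gene was assigned to any site, since no annotation of assembly Zv8 was used here.

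H3K27ac accompanied Cdx4 peaks more often than Sall4 peaks. An H3K27ac domain overlapped 1579 Cdx4 peaks (30.6%, exact 95% interval 29.3 to 31.8%) and 1226 Sall4 peaks (12.6%, 11.9 to 13.3%). Shifted peaks reached a mean of 15.3 and 22.4 peaks and at most 33 and 46. The gap followed the presence of Cdx4. Sall4 peaks that overlapped a Cdx4 peak lay in H3K27ac domains in 32.3% of cases (749 of 2317), and those with Sall4 alone in 6.42% (477 of 7430). Cdx4 peaks without Sall4 reached 28.3% (796 of 2815) and Cdx4 peaks with Sall4 33.3% (783 of 2351). The Cdx4 share exceeded the Sall4 share by 18.0 percentage points (block bootstrap 95% interval 16.7 to 19.3; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 14 comparisons, p = 4.65e-150). Sites of Cdx4 alone exceeded sites of Sall4 alone by 21.9 points (19.9 to 23.7, adjusted Fisher's exact p = 6.71e-174). That comparison of single-factor sites was added after the data were seen. With only the 906 H3K27ac domains over 500 bp wide, 6.79% of Cdx4 peaks and 2.97% of Sall4 peaks lay in a domain, so the differences were smaller in points (3.83 and 4.73) while the ratio of the Cdx4 to the Sall4 share was 2.29, against 2.43 with all domains. Peaks within the list of 1 library are not replicates, and these p-values compare the lists, not conditions. In the comparison of whole lists the 2274 overlapping pairs count on both sides, although Fisher's exact test takes the 2 sides as independent.

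**Figure D1:**
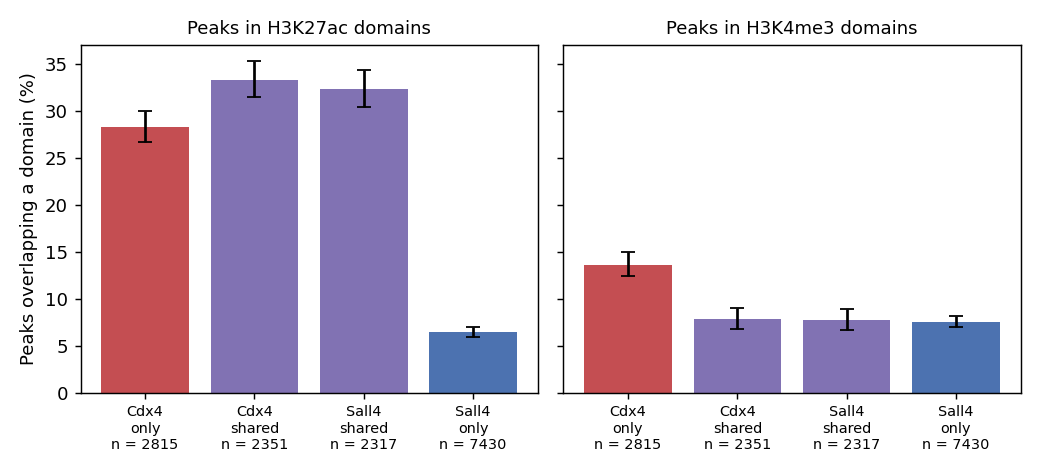
Percent of peaks overlapping an H3K27ac domain (left) or an H3K4me3 domain (right) for Cdx4 and Sall4 peaks with (shared) and without (only) an overlapping peak of the other factor. Bars are shares of the n peaks named below them and error bars exact binomial 95% intervals. Sall4-only peaks had the lowest H3K27ac share, 6.42%, and Cdx4-only peaks the highest H3K4me3 share, 13.6%.

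Over the whole Cdx4 list, the H3K27ac difference between shared and Cdx4-only peaks was small, and it changed sign with peak score. Score groups here are 4 equal groups of each list ranked by score. Shared peaks exceeded Cdx4-only peaks by 5.03 points (2.45 to 7.74, adjusted Fisher's exact p = 1.31e-04). In the top score group of the Cdx4 list the order was the opposite, with 43.8% of shared peaks and 58.3% of Cdx4-only peaks in H3K27ac domains, a difference of -14.5 points (-20.4 to -9.06). In the next groups down the differences were 0.863 points (-4.31 to 6.19) and 6.25 points (1.27 to 11.3). In the bottom score group shared peaks led, with 22.9% against 15.2%, by 7.71 points (3.02 to 12.6). Shared peaks were more common at high scores, where H3K27ac shares were also higher. The difference over the whole list therefore mixes score with sharing and does not show a gain with Sall4 at equal score. The difference was -4.92 points in the better-scoring part of the list split at the median, and it was 0.723 points (-0.796 to 2.25) with domains over 500 bp alone. The Sall4 list showed no reversal of this kind. Its shared peaks exceeded its Sall4-only peaks by 25.9 points (24.0 to 27.9), and by between 20.5 and 30.6 points within each score group. With domains over 500 bp alone, the difference in the Sall4 list was 5.17 points (3.95 to 6.36).

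H3K27ac coverage was concentrated at the peak centres. A domain covered the centre of 27.3% of Cdx4-only peaks, 30.8% of shared peaks and 5.94% of Sall4-only peaks. At -1000 bp along the assembly, coverage of Cdx4-only peaks was 2.49%. Of the H3K27ac domains, 3693 of 4599 (80.3%) were no wider than 500 bp, and 1158 of these (31.4%) held a Cdx4 peak, against 28.3% of the wider domains. In such narrow domains the domain's middle lay a median of 47.5 bp (bootstrap 95% interval 43.5 to 50) from the Cdx4 peak centre and 39.5 bp (35.5 to 44.5) from the Sall4 peak centre, in both cases toward higher coordinates. Of the H3K27ac domains in all, 1414 (30.7%) held a Cdx4 peak and 1094 (23.8%) a Sall4 peak.

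**Figure D2:**
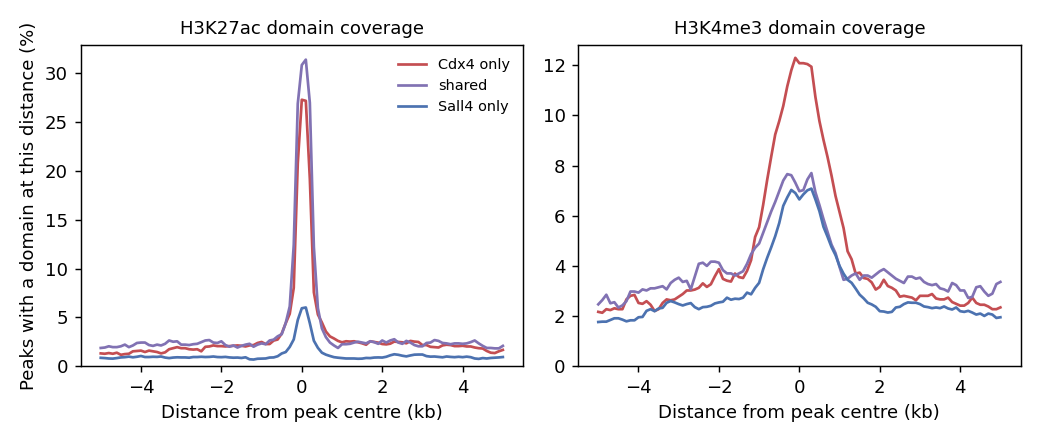
Percent of peaks with an H3K27ac domain (left) or an H3K4me3 domain (right) at each distance from the peak centre, in kb along assembly coordinates, for Cdx4-only, shared and Sall4-only peaks; the vertical scales differ. H3K27ac coverage of Cdx4-only peaks fell from 27.3% at the centre to 2.49% at -1000 bp, and H3K4me3 coverage from 12.1% to 5.54%.

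H3K4me3 was less frequent than H3K27ac at Cdx4 peaks, and most frequent where Cdx4 was present without Sall4. H3K4me3 domains overlapped 567 Cdx4 peaks (11.0%, exact 95% interval 10.1 to 11.9%) and 739 Sall4 peaks (7.58%, 7.06 to 8.13%). Shifted peaks gave means of 67.3 and 123.8 peaks. Among Cdx4 peaks, 13.6% of those without Sall4 and 7.83% of those with Sall4 lay in an H3K4me3 domain. The share of shared peaks was lower by 5.78 points (difference -5.78, block bootstrap 95% interval -7.56 to -3.97, adjusted Fisher's exact p = 3.17e-11). Within the Cdx4 score groups, from top to bottom, the difference was -3.83, -9.52, -5.54 and -2.63 points. Only the interval of the bottom group included 0 (-6.44 to 1.09). Among Sall4 peaks the shares were 7.77% with and 7.52% without Cdx4, a difference of 0.245 points whose interval included 0 (-1.13 to 1.57). From the top to the bottom score group that difference was -1.79 (-3.58 to 0.114), 0.353, 2.30 and 7.65 points (3.18 to 12.5), and only the interval of the bottom group excluded 0. In the better-scoring part of the Sall4 list split at the median it was -1.71 points, with an interval that only just excluded 0 (-3.22 to -0.181). Among shared Sall4 peaks the share was 3.99%, 9.30%, 11.1% and 13.8% from the top to the bottom score group. The Cdx4 list exceeded the Sall4 list by 3.39 points (2.51 to 4.30, adjusted Fisher's exact p = 1.02e-11), where shared sites again count on both sides.

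Most peaks of both factors lay outside the called domains of both marks. Depth and thresholds are unknown, so the lack of a called domain is not the lack of the mark. No domain of either mark overlapped 63.0% of Cdx4 peaks (3256 of 5166) and 81.3% of Sall4 peaks (7920 of 9747). Sites over 5 kb from every domain made up 43.6% of Cdx4 peaks, 60.8% of Sall4 peaks and 67.1% of Sall4-only peaks. Among the 2253 such Cdx4 peaks, 943 (41.9%) overlapped a Sall4 peak.

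Peaks with higher scores were more often shared and more often in H3K27ac domains. The score was the authors' own and ranked peaks within a list only. In the Cdx4 list, 60.1% of the top score group and 30.1% of the bottom group overlapped a Sall4 peak, a difference of 30.0 points (26.3 to 33.4). In the Sall4 list, 43.2% and 11.9% overlapped a Cdx4 peak. The share of Cdx4 peaks in H3K27ac domains was 49.6% in the top score group and 17.5% in the bottom group, a difference of 32.1 points (28.2 to 35.9). For Sall4 it was 18.0% and 8.33%, a difference of 9.68 points (7.62 to 11.7). The H3K27ac share of Sall4 peaks that overlapped Cdx4 was not higher at higher scores, at 29.6% in the top score group and 35.3% in the bottom group. Over all peaks of a list, H3K4me3 shares had no steady trend with score and were highest in the middle groups. From the top to the bottom score group they were 7.20%, 11.9%, 14.8% and 10.1% of Cdx4 peaks and 5.01%, 9.03%, 9.20% and 7.10% of Sall4 peaks. The top minus the bottom group was -2.86 points for Cdx4 (-5.60 to -0.303) and -2.09 points for Sall4 (-3.38 to -0.667). Between the top and bottom of 10 equal groups, which hold fewer peaks, both H3K4me3 differences kept their direction. They were -2.13 and -0.923 points, with intervals that included 0.

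**Figure D3:**
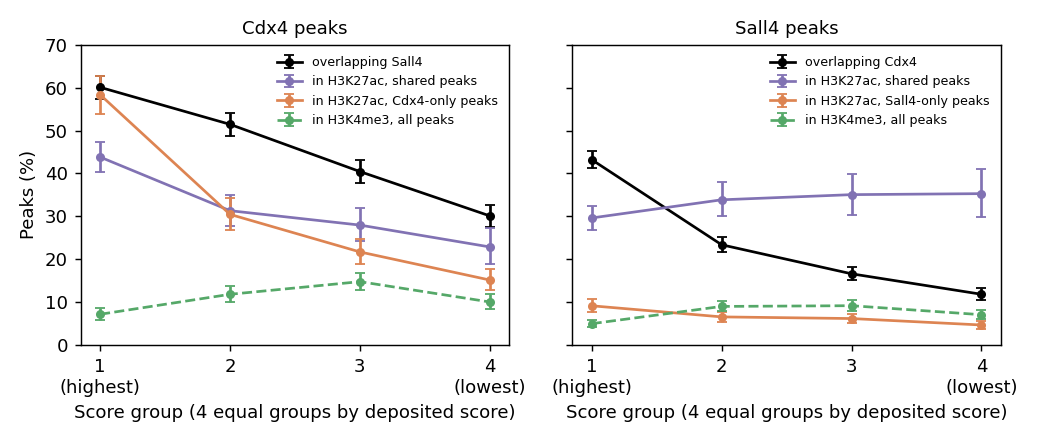
Percent of Cdx4 peaks (left) and Sall4 peaks (right) per score group, the list being ranked by the deposited score and divided into 4 equal groups, that overlapped the other factor, lay in H3K27ac domains (shared and single-factor peaks drawn apart) or lay in H3K4me3 domains; error bars are exact binomial 95% intervals. Among Cdx4-only peaks the H3K27ac share fell from 58.3% in the top score group to 15.2% in the bottom group.

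The marks overlapped each other at a minority of H3K27ac domains. An H3K4me3 domain overlapped 1126 of 4599 H3K27ac domains (24.5%, exact 95% interval 23.2 to 25.8%), against a mean of 85.9 and at most 119 in shifts. Conversely, 1073 of 19401 H3K4me3 domains (5.53%) overlapped an H3K27ac domain. Overlap with H3K4me3 was 21.2% for H3K27ac domains up to 500 bp wide and 38.0% for wider ones. The widest H3K27ac domain, 6599 bp on chromosome 23 at 37024700 to 37031298, held 7 Cdx4 and 6 Sall4 peaks. The next 4 in width held 0 peaks of either factor, on chromosome 6 at 42855800 to 42861398, chromosome 12 at 27462900 to 27468298, chromosome 23 at 8816200 to 8821498 and chromosome 21 at 39194300 to 39199098. The widest H3K4me3 domains, 5399 bp on chromosome 7 at 7067300 to 7072698 and 5299 bp on chromosome 25 at 36203700 to 36208998, held 1 Cdx4 and 1 Sall4 peak respectively.

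Peaks of both factors were clustered, and most clusters of Cdx4 peaks were also clusters of Sall4 peaks. At least 5 Cdx4 peaks fell in each of 161 windows of 100 kb, which held 23.0% of all Cdx4 peaks, against a mean of 11.8 and at most 16 windows for peaks placed at random. Sall4 had 491 such windows with 38.1% of its peaks, against a mean of 28.6 and at most 42. With only the 5166 best-scoring Sall4 peaks, as many as Cdx4 had, there were 231. Of the dense Cdx4 windows, 131 (81.4%) were also dense in Sall4, where independent placement of dense windows would give 5.50. Overlapping peaks count in both lists, so the excess in these windows in part restates the overlap of the peaks. The same windows were 26.7% of the dense Sall4 windows. With 161 dense Cdx4 windows against 491 for Sall4, that share was bound to be low, so it was not read as a difference in binding. The densest Cdx4 window, on chromosome 23 at 35100001 to 35200000, held 26 Cdx4 peaks, 12 Sall4 peaks, 20 H3K27ac domains and 13 H3K4me3 domains. Adjacent windows on chromosome 3 from 20600001 to 20800000 held 20 and 18 Cdx4 peaks and 14 and 16 Sall4 peaks. A window on chromosome 23 at 37000001 to 37100000, around the widest H3K27ac domain, held 18 Cdx4 and 20 Sall4 peaks. Other dense windows held mainly Sall4, such as chromosome 4 at 16800001 to 16900000 with 22 Sall4 and 3 Cdx4 peaks and chromosome 9 at 12900001 to 13000000 with 18 and 2. These windows were named after their counts were seen.

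**Figure D4:**
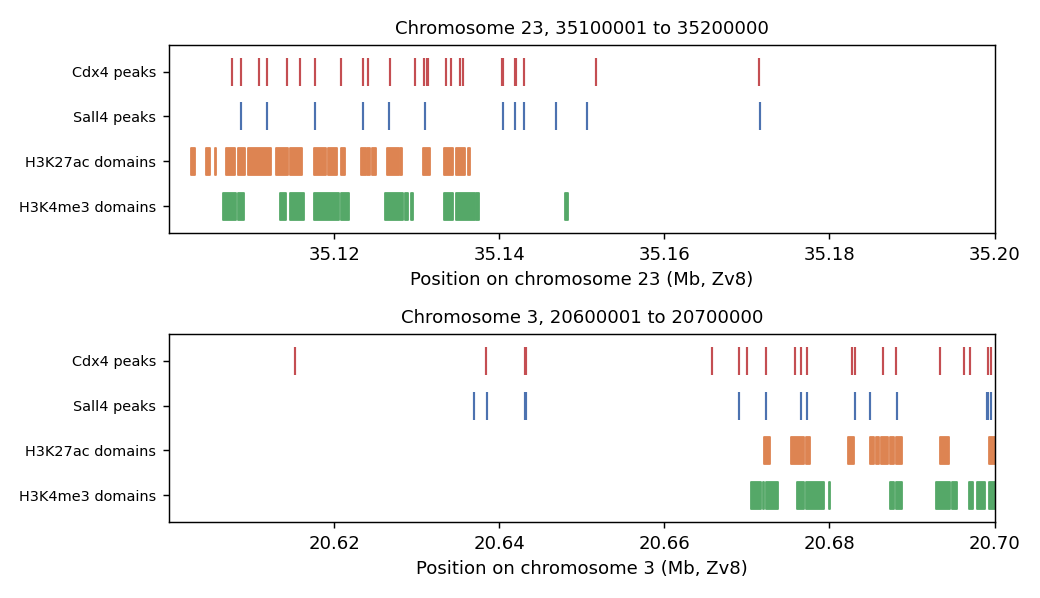
Positions of Cdx4 and Sall4 peaks (ticks) and H3K27ac and H3K4me3 domains (bars, to scale) in windows of 100 kb on chromosome 23 (top) and chromosome 3 (bottom), in Mb of assembly Zv8. The chromosome 23 window held 26 Cdx4 and 12 Sall4 peaks, of which 11 Cdx4 peaks overlapped a Sall4 peak, and the chromosome 3 window 20 and 14, of which 10 did.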

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

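Some tests were chosen only after the result was seen. They were those of the 100 top-scoring peaks, of centring after removal of each group's median offset and of Sall4-only against Cdx4-only peaks. The comparisons within score groups were also chosen only after the result was seen. The H3K27ac comparison of the Cdx4 and Sall4 lists at equal numbers of top peaks was set in advance. Only its use as a test of list length came later. Effects of the same contrast differed between the Cdx4 and the Sall4 list in 3 cases, by a block bootstrap of the difference itself. The gain in H3K27ac share from single-factor to shared peaks differed by -20.9 points (Cdx4 list minus Sall4 list, 95% interval -22.9 to -18.9). The same gain for H3K4me3 differed by -6.02 points (-7.45 to -4.55). The gain in H3K27ac share from the bottom to the top of 4 score groups differed by 22.4 points (18.4 to 26.2). The Sall4 shares were lower throughout, and the ratio of top to bottom share differed less, at 2.84 for Cdx4 and 2.16 for Sall4. Shared peaks are nearly the same sites in both lists, so the first 2 cases mainly restate that Cdx4-only and Sall4-only peaks differed, by 21.9 points for H3K27ac and 6.08 points for H3K4me3. The corresponding contrasts between score groups for H3K4me3 (-0.771, -3.30 to 2.12) and for overlap with the other factor (-1.40, -5.75 to 2.84) had intervals that included 0.

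The pattern behind these values is that H3K27ac domains, narrow ones and those over 500 bp wide, overlapped Cdx4 peaks more often than Sall4 peaks. The longer Sall4 list is argued against as the source, because with equal numbers of top peaks the Cdx4 share was still 15.2 points higher (13.8 to 16.5), whereas chromatin that any precipitation enriches stays open: best-scoring Sall4-only peaks lay in H3K27ac domains 0.157 times as often as best-scoring Cdx4-only peaks, but taking single-factor peaks leaves out the sites such chromatin would give. Only 58.0% of the 100 top-scoring Cdx4 peaks (exact 95% interval 47.7 to 67.8) overlapped an H3K27ac domain. If the deposited score follows read number, this argues against reads of the Cdx4 precipitation carried into the H3K27ac library as the whole source. The bound for this test was set after the shares were seen. Against it, the share rose from 17.5% in the bottom to 49.6% in the top score group of the Cdx4 list, which such reads would also give. A contribution of such reads stays open. The centring of Cdx4 peaks in narrow domains (median distance 0.298 of the half-width) lay between the bounds set in advance. The correlation of Cdx4 and domain scores (rho 0.180, 0.12 to 0.239) lay just under the bound set in advance for arguing against such reads. Its interval crossed that bound, and Sall4 gave a similar rho of 0.223 (0.156 to 0.294), so it was not taken to decide the question. Cdx4-only peaks were nearer the middle than Sall4-only peaks only once each group's own median offset was removed (0.152, 0.140 to 0.165, against 0.292, 0.246 to 0.333). Before removal the values were 0.311 and 0.339, with overlapping intervals. Small acetylated elements around Cdx4 sites could give this centring as well as such reads. Acetylation at sites bound by Cdx4 is a biological explanation that was not tested. Lists from 1 stage do not show whether binding or acetylation came first. With 1 H3K27ac library this explanation cannot be told apart from the explanations left open.

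The overlap of Cdx4 and Sall4 peaks is the second pattern. A common location in the called histone domains is argued against as its source, because Cdx4 peaks over 5 kb from every called domain still overlapped Sall4 peaks 113-fold above shifts. Dense tracts and unplaced scaffolds are argued against as the whole source as well. On assembled chromosomes outside dense windows the excess was 404-fold (1056 of 3027 Cdx4 peaks, 34.9%). That fold is set against a mean of only 2.62 overlaps in shifts. The overlapping share was lower than the 46.3% on all assembled chromosomes, so overlap was more frequent inside dense windows. Repeats outside dense windows were not tested. Background of the shared anti-Myc antibody could tie the scores of a pair together. Their correlation of 0.255 (0.210 to 0.299) lay just under 0.3, the bound set in advance for arguing against such background. It cannot decide the question, because no replicate or untagged library used here shows what correlation a common source would give. Such background may account for some or all pairs, including strong sites with no called domain nearby. An anti-Myc precipitation from untagged embryos was not analysed here, and binding of both factors to the same sites remains a hypothesis.

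The third pattern is the higher H3K4me3 share of Cdx4 peaks. The greater length of the Sall4 list, which would add weak peaks, is argued against by the comparison of equal numbers of top peaks, where the difference was 3.64 points (2.54 to 4.75). A difference in depth or in peak threshold between the libraries was not tested, and neither was any biological explanation.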

How the results depend on the processing

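Alternatives with H3K27ac domains over 500 bp wide, with peaks widened to 200 bp, and for Cdx4-only against Sall4-only peaks were chosen only after the result was seen. For 23 results, 77 alternatives were computed (63 planned, 14 added): 70 kept the direction and the side of the threshold, 3 reversed, 3 kept the direction but lost the call, and 1 count moved by over 1.5 times. With the better-scoring part of each list split at the median, the H3K27ac difference between shared and Cdx4-only peaks reversed to -4.92 points, in keeping with the reversed order in the top score group, and the H3K4me3 difference between shared and Sall4-only peaks, not called before, went to -1.71 points; with equal numbers of top peaks the latter was -1.27 points (-2.72 to 0.176), and the cause was not tested. With H3K27ac domains over 500 bp alone the first of these was 0.723 points, with fewer domains to overlap. With 10 score groups in place of 4, which hold fewer peaks, the H3K4me3 differences by score were -2.13 points for Cdx4 and -0.923 for Sall4. Dense Sall4 windows numbered 231 with as many top peaks as Cdx4, a setting that changes both the number and the scores of the peaks; the cause was not tested.

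The excess of overlapping Cdx4 peaks over their background kept its direction in each of 8 alternatives, from 44.1-fold (centres within 500 bp) to 316-fold (assembled chromosomes), with 34.9 to 52.8% of peaks overlapping. Placement near histone domains as the background gave 84.7-fold. Fold values thus depend on the overlap definition, the sequences used and the background. With 1 list per target, leaving out a library and paired fits were not possible. Analyses of start sites, gene lists and motifs were not run for want of an annotation of the same assembly. Depth is unknown, and with it how many weaker peaks each list lacks.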

Other observations

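The comparison of pairs split by each factor's score was chosen only after the result was seen, as were the regions below. Chromosome 4 stood apart from the other 24 assembled chromosomes. Its second part, beyond 35.8 Mb, the midpoint of the length reached, held 4 of its 142 Cdx4 peaks (2.82%, exact 95% interval 0.773 to 7.06%) and 5 of its 276 Sall4 peaks (1.81%, 0.591 to 4.18%). On the other chromosomes this share ranged from 28.8 to 70.7% for Cdx4 and from 32.7 to 68.4% for Sall4. H3K27ac domains were also rare there (14 of 142, 9.86%, against 41.9 to 65.9% elsewhere). H3K4me3 domains were not, with 319 of 856 (37.3%) in that part, against 27 to 59.4% elsewhere. Chromosome 4 had the lowest density of Cdx4 peaks, 1.98 per Mb, and chromosome 23 the highest, 6.04 per Mb.

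Scaffold Zv8_NA542 carried 19 Cdx4 peaks within 79.4 kb, with scores of 27 to 78, beside 1 Sall4 peak, 0 H3K27ac domains and 0 H3K4me3 domains. It was the only one of the 10 windows densest in Cdx4 with fewer than 11 Sall4 peaks. The site on chromosome 20 near 33284797, top of the Sall4 list and next to the top of the Cdx4 list, lay 13599 bp from the nearest domain of either mark, and it was 1 of 6 among the 10 top-scoring Cdx4 peaks that lay outside H3K27ac domains, 2 of them by less than 300 bp.

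A hypothesis was that acetylation at sites bound by both factors may go with the strength of Cdx4 rather than of Sall4 binding. Among the 2274 pairs, 40.1% of those with the higher Cdx4 scores and 25.3% of those with the lower lay in H3K27ac domains. By Sall4 score the shares were 30.3% for the higher and 35.4% for the lower. The contrast between the splits was 19.9 points (block bootstrap 95% interval 15.1 to 24.9). The hypothesis came from the shares by score at these same sites, so the contrast describes them and does not test it. Reads of the Cdx4 precipitation in the H3K27ac library could give the same contrast, and their contribution stays open (0.152 of the half-width for Cdx4-only peaks).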
